A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

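The series holds 24 libraries of 1 genotype, Mer2-Myc with an ars deletion per the labels, although the sample titles also carry the letters WT. Per the labels' protocols, diploid cells were grown in a pre-sporulation medium, moved to potassium acetate, collected at 12 times and fixed with 1% formaldehyde. Mer2 was pulled down with an antibody against Myc, and sheared chromatin from the same time served as input. Samples were grouped by assay and time as the labels give them, which leaves 1 library per group.

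3 deposited tables were used, each with a value per base and time point. The ChIP and input tables hold whole-number read coverage, a signal that the authors deposited without normalization, since its mean differs between libraries. The third table holds values that the authors call scaled coverage, treated here as a score because its unit is not stated. From the values, each deposited score equals ChIP over input coverage times 1 factor per library minus 1 constant per library, with residuals at the level of rounding. The constant was 0 at 0, 0.5 and 1 h and the scores are partly below 0 from 1.5 h on. How the factors and constants were chosen is not given in the sources used here, so comparisons of amounts between times rest on the authors' scaling. The submitters' processing notes name cutadapt, BWA, Picard and bedtools and the genome build sacCer2, without versions, and the chromosome lengths in the tables are those of that build. Duplicate removal, read length and fragment extension are not stated, so coverage was not turned into read numbers and no counting interval is given. Repeats and duplicates can raise or lower coverage at a region in both libraries alike, which division by the input reduces.

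Coverage was averaged in 1 kb bins. Bins were kept when their mean input lay between 0.25 and 4 times the genome median and they lay outside the ribosomal DNA, which was taken as the widest stretch of high input on chromosome XII. This left 11838 of 12079 bins. For onset and the replication index the same limits were applied to bins of 10 kb, so that a kept bin can hold 1 kb bins outside them. Density of a region was its mean ChIP coverage over the genome mean, divided by the same quantity in the input of that time. The mean of 3 to 5 h is the mean over the libraries at 3, 3.5, 4, 4.5 and 5 h. Peaks were local maxima of density in 100 bp steps, smoothed over 500 bp, at 2 or more times the genome mean and 1 kb or more apart. Onset was the time at which the scaled signal had covered 50% of its rise from 0 h to its maximum, by linear interpolation. Differences in onset shorter than the step between samples therefore rest on this interpolation and on the authors' factors. The replication index was the log2 of the mean relative input at 1.5, 2 and 2.5 h over that at 0 h in 10 kb bins. Centromere positions are textbook positions at a precision of 1 kb.

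Comparisons ran across chromosomes, arms or bins within libraries, and none tested one time against another by replicates. Correlations with length used 100000 permutations. The 3 short chromosomes were compared with the other 13 by an exact permutation test over 560 choices. Regions were compared with the rest of their chromosome by exact sign-flip tests, with the log2 values of both ends of a chromosome averaged. Relations across bins used 10000 circular shifts along the genome, because neighbouring bins resemble each other. For 10 kb bins these shifts were drawn with repeats, since there are fewer distinct shifts than bins (1201 or 1107). A p-value below the inverse of the number of bins is therefore finer than the distinct shifts resolve. Intervals for the arms of chromosome III came from 2000 bootstrap samples of 10 kb blocks. All tests were two-sided except ranks among 32 arms, which are one-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 12 times. The threshold was 0.05. The bootstrap intervals for the arms of chromosome III were not part of the plan, which held only the rank among the 32 arms. The tests of overlap with 0 h summits, of onset by chromosome and of 0 h against later bin densities were not planned either. Further tests are marked below where they were added or written down later. The remaining tests, the alternatives listed as planned and the rule for named regions were fixed before the data were examined.

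The regions named are each of the 16 chromosomes, both arms of chromosome III and the 2 highest and 2 lowest arms. To these come the 10 highest peaks outside the ribosomal DNA, the 5 lowest 10 kb bins, and the 5 earliest and 5 latest bins by onset. Other regions were named after their values were seen, as the extremes of a comparison: the right arms of chromosomes IX and VI for the replication index, chromosomes VI, XV and II for the gap between their arms, and chromosomes singled out for their ends or pericentromeres. Gene lists fixed beforehand and the position of peaks relative to genes were not analysed here, since the only gene table at hand belongs to another build and its coordinates were not used.

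Methods were tested on simulated coverage of 16 chromosomes with 198 planted peaks. A planted log2 excess of 0.8 on the short chromosomes came back as 0.79, one of 0.5 at pericentromeres as 0.46 and one of -0.6 at ends as -0.74. These recoveries used simulated scaled values with the known background subtracted. The density of ChIP over input, on which the results rest, was not tested for these quantities. A planted delay of 0.5 h of the left arm of chromosome III came back as 0.50 h. This delay equals the step between samples during the rise, so recovery of a shorter one was not tested. All simulated peaks were found (100%), and 88.4% of called peaks lay within 1 kb of a simulated one. The planted peaks shared the same set amplitude on an even background, so recovery of weaker peaks was not tested. Null relations passed the threshold in 5% of simulated length relations and 3% of simulated bin relations. The simulated 0 h library gave 0 peaks, unlike the measured one. Alternatives covered the bin size, ChIP without input, the scaled values, peak thresholds, region widths, chromosomes or times left out, the index and the onset rule. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.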

Results

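Mer2 is a chromosomal protein that budding yeast needs to make the DNA double-strand breaks that start meiotic recombination. Its binding was followed in a synchronous meiotic culture of diploid Saccharomyces cerevisiae by chromatin immunoprecipitation of Myc-tagged Mer2 and sequencing (ChIP-seq). Samples were taken at 12 times, at 0, 0.5, 1, 1.5, 2, 2.5, 3, 3.5, 4, 4.5, 5 and 6 h in meiosis. Each time has 1 ChIP library and 1 input library, the input being the chromatin before the pull-down, so there was no replicate at any time. Errors are therefore the SD over the 5 times from 3 to 5 h or over the 16 chromosomes, and p-values describe regions of this culture and not separate cultures. Mean read coverage per base was 9.83 at 0 h, 1.02 at 0.5 h and 4.77 at 1 h in the ChIP libraries, and lay between 42.5 and 148.2 from 1.5 h on. The input libraries had mean coverages between 57.9 and 147.9. Density below means ChIP coverage over input coverage, each divided by its own genome mean, so that a log2 density of 0 is the genome average of that library.

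The first question was when Mer2 bound and left the chromosomes. The mean of the authors' scaled signal was 0.00193 at 0 h and 0.0275 at 2 h. It was highest at 3.5 h, at 0.140, and each of the 16 chromosomes had its highest value at that time. All chromosomes of a library share its factor and constant, so their agreement adds no separate support for that time. By 6 h the mean scaled signal was 0.0183, which is 13.03% of the highest value. The contrast of the profile, the SD of log2 density over 1 kb bins, was 0.42 at 0 h, 0.35 at 1.5 h, 0.79 at 3 h and 0.49 at 6 h. Once formed, most of the pattern along the chromosomes was kept, although ends, pericentromeres and short chromosomes still shifted against the rest, as described below. Profiles of any pair of times from 2.5 to 6 h had Pearson correlations between 0.864 and 0.980 across bins, which are not independent replicates. The 0 h profile correlated with these at -0.206 to -0.117. The contrast of 0.78 at 0.5 h comes from the library with a mean coverage of 1.02. Amounts can be set side by side across times only through the authors' scaling, whose factors are not explained in the sources used here.

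**Figure D1:**
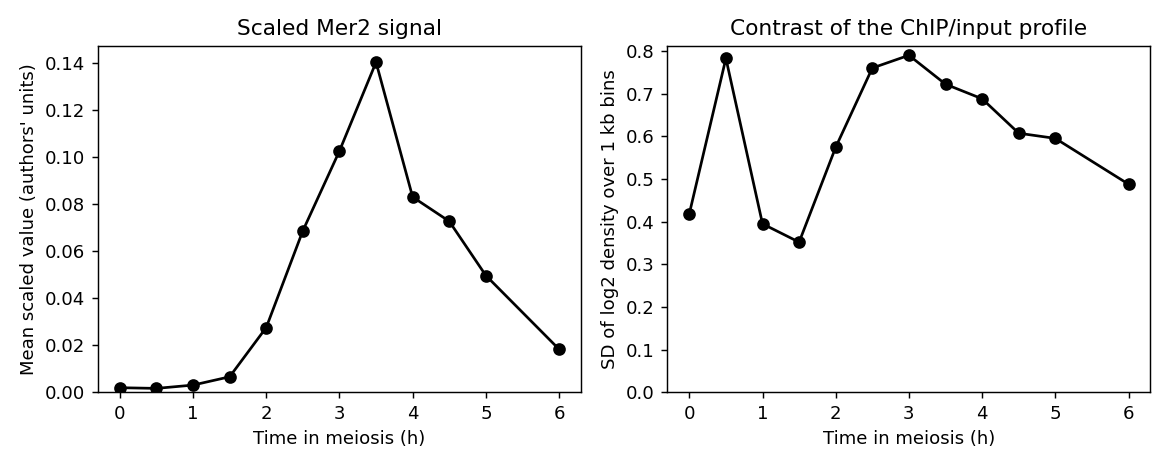
Mean scaled Mer2 signal in the authors' units (left) and SD of log2 ChIP/input density over 1 kb bins (right) against time in meiosis in hours, 1 library per point. The scaled signal is highest at 3.5 h, at 0.140, and the high contrast at 0.5 h is that of the library with a mean coverage of 1.02.

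The next question was where Mer2 bound. In the mean of 3 to 5 h, 651 peaks stood at 2 or more times the genome mean, with a median height of 2.75 and a median spacing of 13.7 kb. The highest peak lay on chromosome VI at 68801 to 68900 (sacCer2), with a density of 11.4 ± 1.04 (SD over 5 times), against 0.942 at 0 h. The second lay on the same chromosome at 216401 to 216500, with 9.22 ± 1.70. Chromosome I held 4 of the 10 highest, at 79701 to 79800 (8.79 ± 0.539), 127001 to 127100 (8.63 ± 0.937), 95401 to 95500 (8.60 ± 1.16) and 171901 to 172000 (8.44 ± 0.626). The remaining 4 were on chromosome XI at 55701 to 55800 (8.77 ± 1.03), XIV at 71401 to 71500 (8.27 ± 0.314), III at 233101 to 233200 (7.75 ± 0.207) and XII at 105201 to 105300 (7.49 ± 0.933). Chromosomes I, III and VI make up 6.77% of the genome and held 7 of the 10 highest and 25 of the 100 highest peaks.

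Summits appeared at their later places early. At 2 h alone 542 peaks were called, of which 379 (69.9%) lay within 500 bp of a summit of the 3 to 5 h mean, and at 1.5 h this held for 81 of 233. The highest peak of chromosome VI already had a density of 10.7 at 2 h, while the XIV peak had 3.97 then and 7.30 at 2.5 h. Windows within 500 bp of the 651 summits covered 6.06% of the usable genome and took 13.6% of the ChIP coverage at 2 h and 12.6% at 6 h, libraries that had no part in choosing the summits, against 5.49% at 0 h. Their share of the input was 5.78% at 2 h and 5.80% at 6 h. The same rule called 555 peaks at 0 h, so a count alone does not separate signal from background. Of the 651 summits, 19 lay within 500 bp of a 0 h summit. This was fewer than the 32.9 (95% range 23 to 44) given by 10000 circular shifts along the genome (two-sided permutation p = 0.011, not planned). Summits at centromeres were an exception. Of the 15 summits within 2 kb of a centromere, on 15 chromosomes, 13 already had a density of 2 or more at 0 h, with a median of 2.83, so these stood out in the background too. Of the other 636 summits this held for 1, and their median at 0 h was 0.894. Genes at the peaks were not analysed here, because no annotation of this build was used.

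Whether short chromosomes carry more Mer2 per kb is a known question of this work. Chromosome I, the shortest, had a log2 density of 0.74 ± 0.07 (SD over 5 times) in the mean of 3 to 5 h, which is 1.67 times the genome average. Chromosome VI followed with 0.49 ± 0.03 and chromosome III with 0.28 ± 0.09. The other 13 lay between 0.06 ± 0.05 and -0.15 ± 0.05. In order these were VIII at 0.06, XI at 0.05, XIV at 0.05, IX at 0.05, X at 0.01, XII at -0.03, II at -0.04, XIII at -0.05, V at -0.08, XV at -0.08, VII at -0.09, XVI at -0.10 and IV, the longest, at -0.15. The order of these 13 depended on the setting. By the median over bins XI was at 0.002 and XIII at 0.01, and with 0 h subtracted VIII was at 0.12 and IX at -0.009. The lead of the short chromosomes was larger at 2 h, when chromosome I reached 1.05, chromosome VI 0.83 and chromosome III 0.40.

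The 3 short chromosomes exceeded the other 13 by 0.53 in the mean of 3 to 5 h and by 0.82 at 2 h. Both differences had an exact permutation p of 0.00179 (two-sided, 560 choices of 3 of the 16), the smallest the choices can give, and the adjusted exact p at 2 h was 0.00238 over the 12 times. From 1.5 to 6 h each of chromosomes I, III and VI lay above each of the other 13, with differences between 0.47 and 0.82. At 0 h the difference was 0.05 and did not pass (exact permutation p = 0.127, adjusted 0.127). At 0.5 and 1 h it was 0.07 and 0.08 (exact permutation p adjusted over the 12 times 0.0312 and 0.0107). Over the 16 chromosomes, log2 density in the mean of 3 to 5 h fell with log10 length (Pearson r = -0.884, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = -0.871, permutation p = 8e-05). Without chromosomes I and VI, the farthest from the median in log10 length, r was -0.844.

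The relation was also computed at single times. At 5 h r was -0.916 (permutation p = 1e-05, adjusted 3e-05 over 12 times; rho = -0.909, adjusted 0.00015), and -0.890 without chromosomes I and VI. At 2 h r was -0.832 (permutation p = 8e-05, adjusted 0.000137; rho = -0.594, adjusted 0.0256), and -0.663 without these 2. At 3 h r was -0.746 (permutation p = 0.00107, adjusted 0.00128), but rho was -0.471 (permutation p = 0.0665, adjusted 0.0887) and r without these 2 chromosomes was -0.343, so the 3 h relation rests on them. Among the 13 longer chromosomes, a subset chosen after seeing the data, r was -0.336 at 2 h (permutation p = 0.265, adjusted 0.398), 0.0443 at 3 h (permutation p = 0.885, adjusted 0.953) and -0.822 at 5 h (permutation p = 0.0007, adjusted 0.00267). The slope of these 13 on log10 length changed by -0.55 from 3 to 5 h (exact swap test, p = 0.0488, adjusted 0.14 over 66 pairs of times), so a difference between these times was not shown. At 0 h r over all 16 was -0.459 (permutation p = 0.074, adjusted 0.074; rho = -0.241, permutation p = 0.368). At 0.5 h it was -0.487 (permutation p = 0.0517, adjusted 0.0564). The relation already passed at 1 h, when the scaled signal was 2.17% of its maximum. There r was -0.733 (permutation p = 0.00074, adjusted 0.00111) and rho -0.594 (permutation p = 0.0171, adjusted 0.0256). The slope per log10 length was -0.14 at 1 h, against -1.27 at 2 h.

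**Figure D2:**
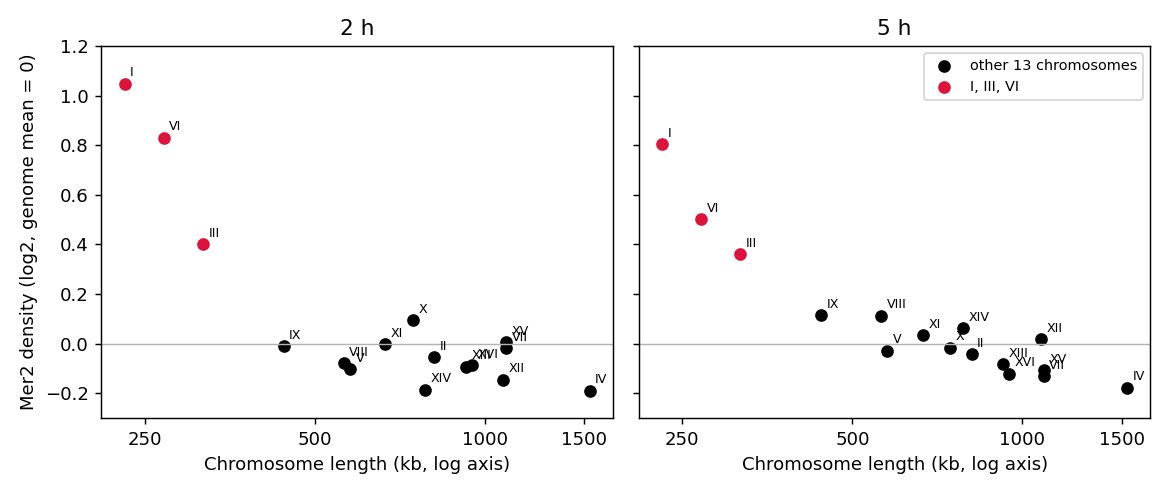
Mer2 density of each chromosome (log2, genome mean 0) against its length in kb on a log axis, at 2 h (left) and 5 h (right), 1 library pair per time. Chromosomes I, VI and III (red) lie at 1.05, 0.83 and 0.40 at 2 h, above all 13 others (black), and the longer chromosomes slope downward at 5 h.

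The genotype label names an ars deletion, without saying where. The left arm of chromosome III was taken as the arm that lacks origins from general knowledge of such strains, and the sources used here do not give this. The left arm had a log2 density of 0.15 ± 0.09 (SD over 5 times) in the mean of 3 to 5 h and the right arm 0.34 ± 0.09. The gap was widest at 2.5 h, at -0.43, with a 95% interval that included 0 (-0.84 to 0.01, bootstrap over 10 kb blocks). At 2 h the left arm stood at 0.11 and the right arm at 0.52, a difference of -0.41 (95% interval -0.76 to -0.07), against 0.05 (-0.16 to 0.27) at 0 h. No other time had a density interval that left out 0. These intervals were not planned and not adjusted over the 12 times. The left arm reached 50% of its rise in scaled signal at 2.63 h and the right arm at 2.42 h, a difference of 0.212 h (95% interval 0.0959 to 0.289). This gap is shorter than the step between samples, and its interval covers the choice of blocks only. Bins of 10 kb from 190001 to 260000 on the right arm had onsets between 2.23 and 2.39 h. Those on the left arm up to 110000 lay between 2.46 and 2.70 h. The latest onsets, 2.79 to 2.90 h, lay from 110001 to 160000, at the centromere and beside it on the right arm. The arm means therefore do not show a left arm that loads last. In the mean of 3 to 5 h the density difference between the arms was -0.19, with an interval that included 0 (-0.58 to 0.17). Gaps between arms of this size were not particular to chromosome III. By size its gap at 2 h was the 3rd of 16 (exact rank p = 0.188), after chromosomes VI (-0.52) and XV (0.48), and its gap in onset the 2nd (exact rank p = 0.125), after chromosome II (0.241 h). This comparison was added after seeing the data.

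Among all 32 arms the left arm of chromosome III had the 10th latest onset (exact rank p = 0.312), and by density it ranked 23rd from the lowest at 2 h. This density rank depended on the setting, at 12 from ChIP alone, 25 from the scaled values, 26 without ends and pericentromeres, and 7 when only arms of middle length were ranked. The 2 arms with the highest density in the mean of 3 to 5 h were the left and right arms of chromosome I, at 0.76 ± 0.07 and 0.70 ± 0.08. The 2 lowest were the right arm of chromosome IX at -0.28 ± 0.18 and the right arm of chromosome IV at -0.20 ± 0.07. From ChIP coverage without input, the left minus right difference of chromosome III at 2 h was -0.69, over 1.5 times the main value. The input of the left arm was 0.827 times that of the right arm at 2 h, which ChIP alone does not divide out.

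The input libraries carry the change in copy number during S phase. The replication index, the log2 of relative input at 1.5, 2 and 2.5 h over that at 0 h, was lowest of all 32 arms on the left arm of chromosome III, at -0.08 (exact rank p = 0.0312, the smallest that 32 arms allow). Relative input of this arm was 0.956 at 0 h, 0.866 at 2 h and 0.971 at 6 h. That of the right arm was 1.05 at all 3 of these times. The highest indices were those of the right arms of chromosomes IX (0.06) and VI (0.05). With 1 input library per time, the index has no error of its own.

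**Figure D3:**
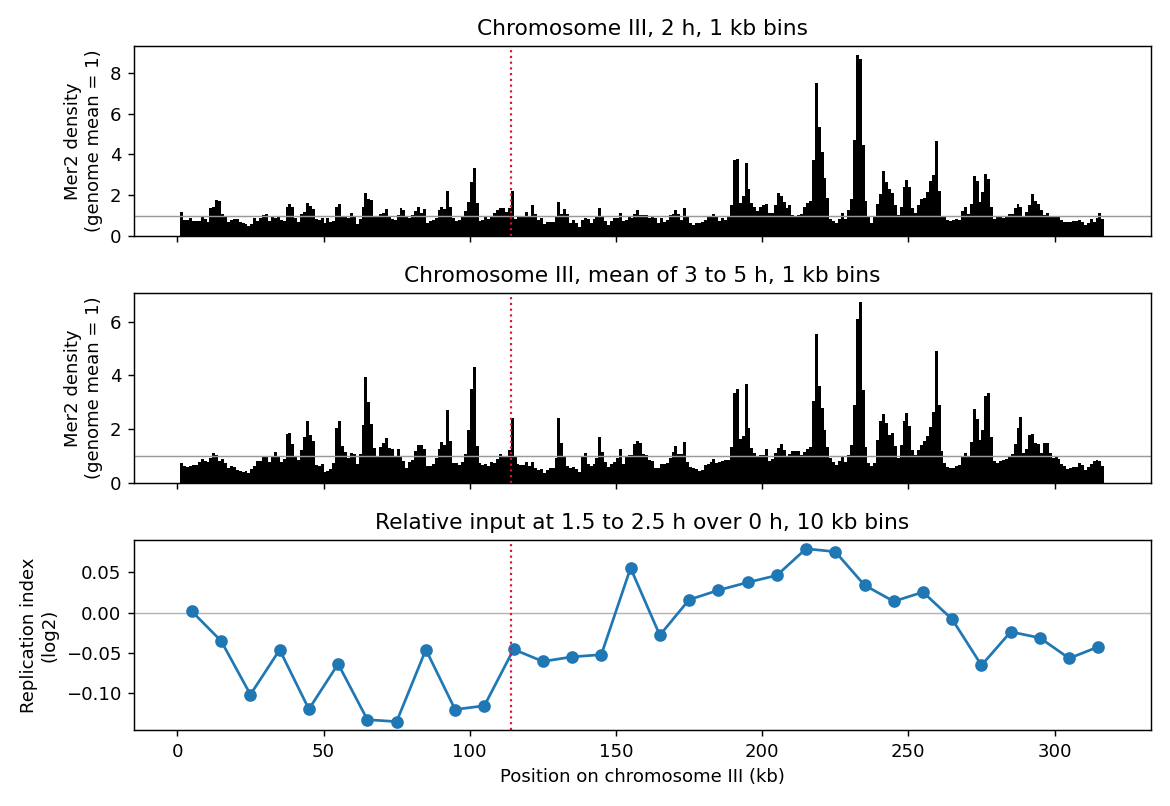
Mer2 density in 1 kb bins along chromosome III (genome mean 1) at 2 h and in the mean of 3 to 5 h, above the replication index (log2) in 10 kb bins, against position in kb, with the centromere as a dotted line. The right arm holds the highest bins at 2 h, and the index of the left arm averages -0.08.

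Regions around centromeres differed from the rest of their chromosome. Within 10 kb of the centromere, density at 1.5 h exceeded the rest of the chromosome by a log2 mean of 0.77 ± 0.25 (SD over 16 chromosomes), which is 1.70 times, with all 16 higher. Chromosomes XII (1.16), IX (1.09) and XV (1.09) had the largest excess and chromosome III (0.25) the smallest. The mean was 0.54 ± 0.36 at 2 h (15 of 16 higher) and -0.28 ± 0.31 at 3 h (14 of 16 lower). At 0 h it was 0.03 ± 0.18, but the central 2 kb on each side of the centromere were already higher by 0.33 ± 0.23 then (15 of 16). Without this centre, a setting added after seeing the data, the means were -0.05 ± 0.21 at 0 h, 0.70 ± 0.24 at 1.5 h (16 of 16 higher) and -0.31 ± 0.34 at 3 h (15 of 16 lower). The centre itself stood at -0.19 ± 0.36 at 3 h (exact sign-flip p = 0.0536, not adjusted, as for the values that follow), and above the rest at 0.19 ± 0.20 at 4.5 h (exact p = 0.00128, 13 of 16 higher), 0.19 ± 0.21 at 5 h (exact p = 0.0018) and 0.13 ± 0.18 at 6 h (exact p = 0.0149). For the full 10 kb, two-sided exact sign-flip tests over the 16 chromosomes, adjusted over 12 times, gave p = 0.000183 at 1.5 h, 0.000458 at 2 h, 0.00598 at 3 h and 0.525 at 0 h. The excess also passed before 1.5 h, at 0.14 ± 0.15 at 0.5 h (adjusted exact p = 0.00535, 13 of 16 higher) and 0.24 ± 0.11 at 1 h (adjusted exact p = 0.000183, 16 of 16 higher). Without the centre it did not pass at 0.5 h, at 0.05 ± 0.20 (exact sign-flip p = 0.334, not adjusted, 11 of 16 higher). At 1 h it was 0.15 ± 0.10 without the centre (exact sign-flip p = 6.1e-05, not adjusted, 15 of 16 higher). At 2.5 h the mean over the full 10 kb, -0.04, did not pass (exact p = 0.694, adjusted 0.694). In the mean of 3 to 5 h pericentromeres were at -0.17 ± 0.23 (exact p = 0.00955, 11 of 16 lower), and at 6 h at -0.16 ± 0.12 (adjusted exact p = 0.000244, 15 of 16 lower).

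Chromosome ends were low once Mer2 had bound. The outer 20 kb had a log2 density 0.09 ± 0.12 (SD over 16 chromosomes) above the rest at 0 h (adjusted exact sign-flip p = 0.0114, 15 of 16 higher). From 2 h on the ends were lower on all 16 chromosomes, with means of -0.47 ± 0.33 at 2 h, -0.86 ± 0.24 at 3 h and -0.37 ± 0.23 at 6 h (exact sign-flip p = 3.05e-05 at each time, the smallest the test can give, adjusted 4.58e-05). In the mean of 3 to 5 h the ends of chromosomes I (-1.21 ± 0.09, SD over 5 times) and VI (-1.18 ± 0.17) were the farthest below the rest of their chromosome, and those of chromosome II (-0.38 ± 0.17) the nearest to it. Coverage at ends is affected by repeats, and bins of very low or high input were left out.

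The flanks of the ribosomal DNA, the tandem repeat array on chromosome XII (451401 to 468900 in these files), were also poor in Mer2. The 50 kb on each side had a log2 density of -0.55 ± 0.14 (SD over 5 times) against the rest of chromosome XII in the mean of 3 to 5 h, or 0.682 times. The value was 0.06 at 0 h, -0.72 at 3 h and -0.29 at 6 h. Against the genome mean the flanks were at -0.54, and 0.181% of 9972 window pairs of the same size elsewhere had a lower density. These pairs slide in steps of 1 kb and overlap heavily. They are therefore not separate comparisons, and the share is not a p-value. This is a single locus and no test was made.

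**Figure D4:**
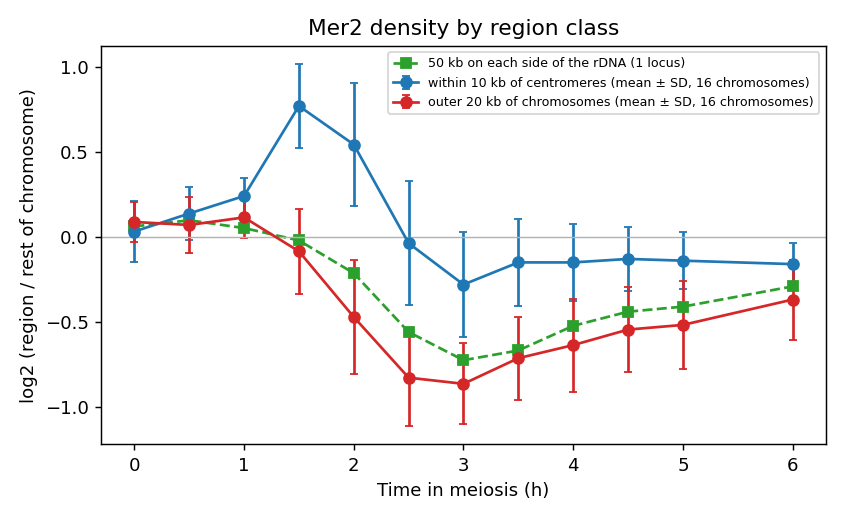
Log2 density of regions over the rest of their chromosome against time in hours: within 10 kb of centromeres and the outer 20 kb of chromosomes (mean ± SD over 16 chromosomes) and 50 kb on each side of the ribosomal DNA (1 locus). Pericentromeres lie at 0.77 at 1.5 h and -0.28 at 3 h, and the ends reach -0.86 at 3 h.

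The 5 lowest 10 kb bins in the mean of 3 to 5 h were on chromosomes VII at 510001 to 520000 (log2 density -1.06 ± 0.12), XII at 490001 to 500000 (-1.01 ± 0.18), XIII at 430001 to 440000 (-1.01 ± 0.13), XV at 380001 to 390000 (-0.97 ± 0.15) and IV at 970001 to 980000 (-0.94 ± 0.12). None of these was near an end; the VII bin was centred 18 kb from its centromere, and the XII bin lay within 50 kb of the ribosomal DNA.

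The time of loading differed between regions of 10 kb. The median bin reached 50% of its rise at 2.60 h, and the 10th and 90th percentiles were 2.35 and 2.76 h. This range is shorter than the step between the samples at 2, 2.5 and 3 h, so it rests on interpolation between single libraries. The 5 earliest bins were on chromosome IX at 340001 to 350000 (2.04 h), VI at 150001 to 160000 (2.07 h) and 160001 to 170000 (2.09 h), XVI at 540001 to 550000 (2.09 h) and VI at 190001 to 200000 (2.10 h). The centres of 4 of these lay 7 to 17 kb from a centromere, and the last lay 47 kb away. The 5 latest were on chromosome XII at 480001 to 490000 beside the ribosomal DNA (4.73 h), X at 740001 to 745742 (3.09 h), XII at 1 to 10000 (3.06 h), XII at 1070001 to 1078175 (3.05 h) and XII at 1060001 to 1070000 (3.05 h), of which the last 4 lie in the outer 20 kb of their chromosome. In the latest bin, that beside the ribosomal DNA, 3 of 10 bins of 1 kb passed the input filter, and the other 7 had inputs between 0.0399 and 0.118 times the genome median, so its value rests partly on bases with little input. The median onset was 2.46 h for 32 pericentromeric bins, 2.70 h for 62 subtelomeric bins and 2.59 h for the other 1107.

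Onset was compared with the replication index across 1201 bins, since both were measured in the same culture. Bins with a higher index did not pass as earlier (r = -0.123, permutation p = 0.109; rho = -0.139, permutation p = 0.0811; 10000 circular shifts, two-sided), and r was -0.125 without the 2 bins farthest from the median index. Bins are not independent replicates. With onset taken at 25% of the rise, r was -0.328 (permutation p = 0.0001, finer than the distinct shifts resolve). With the index taken over the mean of 0 and 6 h, added after seeing the data, r was -0.198 (permutation p = 0.0083).

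By 6 h the scaled signal had fallen to between 12.4% (chromosome VII) and 15.0% (chromosome I) of its highest value. Chromosomes III and VI stood at 14.6% and 13.7%, and the longest, chromosome IV, at 12.5%. The remaining share fell with log10 length (r = -0.866, permutation p = 2e-05; rho = -0.835, permutation p = 0.00012; 16 chromosomes), and r was -0.862 without chromosomes I and VI. This direction depends on the starting time. As 6 h over 4 h, the share rose with length (r = 0.777, permutation p = 0.00055).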

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

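All differences between times in this part were tested after the time courses had been seen. The checks of background, extra copies and ends were also made after. Each time has 1 ChIP library, so these tests cannot tell a change over time from a difference between libraries. Of the 66 pairs of times, 45 passed for pericentromeres, 60 for ends and 48 for the short chromosomes. Neighbouring times passed too, such as 4.5 and 5 h for ends (0.03, exact sign-flip p = 0.00366, adjusted 0.00417). The rank by replication index was planned, but its use with the 1.5 h values as a test of an explanation was chosen after both had been seen. The matched-bin test and the test over the 31 other arms were written down before their results were seen.

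The excess at pericentromeres differed between libraries of different times. It changed by -1.05 on the log2 scale from 1.5 to 3 h (exact sign-flip test over 16 chromosomes, p = 3.05e-05, adjusted 0.000101 over 66 pairs of times). Background of the ChIP at centromeres is argued against as the cause of the excess within 10 kb, since the excess rose by 0.74 ± 0.10 (SE, 16 chromosomes) from 0 to 1.5 h, on 15 of 16, and by 0.75 ± 0.10 without the 2 kb on each side of the centromere, where 0 h peaks lie. Early replication of pericentromeres, as far as the input index measures it, is argued against as the whole cause: over bins matched on the index the excess at 1.5 h was still 0.68 ± 0.07 (SE), against 0.84 over unmatched bins. An early loading of Mer2 near centromeres may remain as a hypothesis, and the separate libraries of 2 h showed an excess of 0.54; no other biological explanation was tested.

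The lead of chromosomes I, III and VI over the other 13 changed by -0.35 from 2 to 3.5 h (exact permutation p = 0.00179, the smallest possible, adjusted 0.00357). Background of the ChIP is argued against, because the 3 chromosomes rose by a mean of 0.71 from 0 to 2 h while the largest rise among the other 13 was 0.12. Extra copies were not seen in the input, with a mean relative input of 1.01 and values between 0.982 and 1.03 over the 12 times. Density is divided by the input, which removes copy number, so these values do not test the lead. A larger share of ends and centromeres is argued against, since without these regions the lead in the mean of 3 to 5 h was 0.64, against 0.53 with them. Both classes were low in that mean, so this outcome followed from values given above and adds no separate support. A preference of Mer2 for short chromosomes may be put forward as a hypothesis, and 3 chromosomes of 1 culture leave features of these particular chromosomes open.

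The left arm of chromosome III had a lower mean density than the right arm at 2 h, a gap exceeded in size on chromosomes VI (-0.52) and XV (0.48). The part of the right arm beside the centromere had later onsets than the left arm, so the gap does not hold for the whole right arm. Background or low coverage is argued against: the difference between arms moved by -0.47 (95% interval -0.86 to -0.04) from 0 to 2 h, starting from 0.05. Late replication of the arm stays open: the arm had rank 1, the lowest, of the replication indices of the 32 arms, but at 1.5 h, when density over bins outside pericentromeres and ends followed this index most closely (r = 0.404), no deficit against the right arm was shown (difference 0.02, 95% interval -0.15 to 0.20) and the arm stood at 0.22. Whether arms that replicate late load Mer2 late in general cannot be told apart from no relation, as r over the 31 other arms was -0.225 (permutation p = 0.222, 95% interval -0.587 to 0.206; rho = -0.184, permutation p = 0.322). No strain with its origins in place was analysed here, so the deletion itself was not tested.

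The deficit at chromosome ends changed by 0.49 from 3 to 6 h (exact sign-flip p = 3.05e-05, adjusted 4.11e-05). Over the same times the contrast of the whole profile fell from 0.79 to 0.49, and the ribosomal DNA flanks moved from -0.72 to -0.29. The loss was not shared by every difference. The lead of the short chromosomes was 0.47 at 3 h and 0.52 at 6 h, with no change shown (exact permutation p = 0.509). A change particular to the ends still cannot be told apart from a loss of contrast shared with other regions.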

How the results depend on the processing

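Of 104 alternative values of the main results, 91 kept their direction and side of the threshold, stayed within their spread or, for peak counts, lay within 1.5 times the main count. The short chromosomes remained above the others under every alternative run (0.43 to 0.66 in the mean of 3 to 5 h, 0.62 to 1.12 at 2 h). The length relation of the mean of 3 to 5 h ranged from -0.906 to -0.740, pericentromeres at 1.5 h from 0.66 to 0.87, ends from -0.82 to -0.55, and the left arm of chromosome III kept the lowest replication index in all 4 alternatives. The alternatives with the 13 longer chromosomes, 0 h subtracted, centromere centres left out, a time left out of the length and short-chromosome means, 0 h summits removed, other indices for onset, and unscaled loss were chosen after seeing the data.

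The following values moved, and the cause was not tested unless stated. The profile contrast of 0.68 became 0.55 in 5 kb bins and 0.89 with the scaled values. The scaled amount left at 6 h was 14.2% by the median and 10.4% at summits, with the maximum at 3.5 h in both. Peak thresholds of 1.5 and 3 times the mean gave 1097 and 269 peaks, by construction. Among the 13 longer chromosomes the 2 h length relation did not pass (r = -0.336). The left minus right difference of chromosome III at 2 h was -0.69 from ChIP alone (density rank 12 of 32 instead of 23). The shift of this difference is that of the input, which was 0.827 times as high on the left arm and which ChIP alone does not divide out. The ribosomal DNA flanks were at -0.70 with the scaled values. Onset against replication passed with 25% of the rise (r = -0.328) and with the index over the mean of 0 and 6 h (r = -0.198). Loss against length reversed when taken from 4 h, with the scaled values (r = 0.777) and without the scaling (r = 0.693).

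No paired analysis was possible because each group has 1 library. The gene list and peak position alternatives were not run, for want of an annotation of this build, nor were onset ranks from ChIP alone or the scaled densities, since onset already uses the scaled values. The shallow ChIP libraries at 0, 0.5 and 1 h limit what can be said of the background.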

Other observations

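The hypotheses of early replication and early Mer2 below were written down before their results were seen, and the indices without the 1.5 h input were added after.

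At 1.5 h, when the scaled signal was 4.68% of its maximum, Mer2 density followed the replication index. Over 1107 bins of 10 kb outside pericentromeres and ends, log2 density at 1.5 h rose with the replication index taken over the mean of 0 and 6 h (r = 0.469, permutation p = 0.0008; rho = 0.505, permutation p = 0.0008; 10000 circular shifts). The p-values at 1.5 h are finer than the distinct shifts resolve. The correlation was 0.274 at 2 h (permutation p = 0.0042), 0.0497 at 2.5 h (permutation p = 0.314), -0.0795 at 3 h (permutation p = 0.0328) and -0.0172 at 5 h (permutation p = 0.708). With the index over 0 h alone it was -0.109 at 3 h (permutation p = 0.0059) and -0.0906 at 3.5 h (permutation p = 0.0178). The relation was thus weakly negative at 3 h, with p-values not adjusted over the times. With the index over the mean of 0 and 6 h, the drop from 1.5 to 5 h was 0.486 in r. This lay outside the 95% range of circular shifts (-0.117 to 0.139). With an index of 2 and 2.5 h over 6 h, which shares no library with the 1.5 h density, r at 1.5 h was 0.478. The same index gave 0.127 at 0 h and 0.159 at 1 h, so part of the relation may lie in the background. These values are consistent with the hypothesis that the earliest Mer2 marks regions that replicate first and that this order is gone by 5 h. Bins of 1 culture are not replicates.

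The background of the ChIP was itself structured. Over 1201 bins of 10 kb the 0 h density correlated with the 1 h density at 0.402 and with the mean of 3 to 5 h at -0.255. No shift reached either value (permutation p = 0.0001 for both, finer than the distinct shifts resolve). These correlations were not planned. Of the 5 lowest bins of the 3 to 5 h mean, those on chromosomes XIII, XV, IV and XII had 0 h log2 densities of 0.66, 0.49, 0.41 and 0.28, and the one on chromosome VII had -0.11.

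Onset was early on chromosomes I and VI. The tests of onset by chromosome in this paragraph were not planned. For chromosomes I, III and VI, the mean onset of these 3 minus that of the other 13 was -0.189 h (exact permutation p = 0.00536), a gap shorter than the step between samples. Chromosomes VI and I had onsets of 2.32 and 2.33 h, the 2 earliest. Chromosome III, at 2.48 h, came after chromosomes XV (2.46 h) and X (2.47 h), and chromosome XII, the latest, had 2.70 h. Over all 16 chromosomes onset did not pass against log10 length (r = 0.475, permutation p = 0.061; rho = 0.156, permutation p = 0.562), and r was -0.109 without chromosomes I and VI.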
